A study of Mus musculus with 8 samples.

How the data were processed

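Single-cell gene expression was measured in mouse LT-HSC, hematopoietic progenitors and LT-HSC cultured for 5 days after induction of an shRNA with doxycycline. The labels give doxycycline (1 ug/mL), TPO (100 ng/mL), SCF (10 ng/mL), 2-mercaptoethanol (50 uM) and BIT (20%) for every library, also for the LT-HSC and progenitors of the first experiment. They give days of knockdown only for the cultures. The deposited values are raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 7.1.0 on build mm10, per the file headers and the submitters' processing notes. The matrices hold 24436 gene entries, including an added mCherry sequence, beside 4 hashtags and, in the first experiment, 7 antibody tags. The deposited barcodes had already been called as cells. The first experiment's barcodes held few cells with 2 hashtags (0.0563% in LT-HSC and 0.156% in progenitors, against 12.8% and 8.51% in the cultures), so multiplets there had apparently been removed before deposit; this was read from the values. The hashtag names RenDim, LowDim, RenBright and LowBright were read as control shRNA (Ren) or Cux1 shRNA (Low) and initial CUX1 low (Dim) or high (Bright). That reading rests on the names and on the series description, and Cux1 UMIs per pool were checked against its shRNA part. No value in the files checks Dim against Bright.

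The libraries held 1825, 10360, 8657 and 8976 barcodes (LT-HSC, progenitor, cultures A and B) and 31827274, 124081010, 138264128 and 126315135 UMIs. Cells with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, and the 2% of cells with the highest doublet score were left out (29, 175, 141 and 142 cells). Cells passing these filters but carrying 2 hashtags were also left out (1, 15, 1060 and 733 cells). Kept cells numbered 1746, 9450, 7118 and 7750, with a median of 15602.5, 10927, 12109.5 and 10177.5 UMIs. In the cultures 122 and 108 of the deposited barcodes, counted before filtering, had very many UMIs (over 1e+05). Each cell was assigned to a hashtag by a mixture model on background-scaled tags with a posterior of at least 0.9. Of kept cells, from which those with 2 hashtags had been removed, 87.3% were called in A and 82.4% in B. Own-tag medians stood above background by unequal margins: in A 77 against 7.15 UMIs (RenDim), 139 against 27.2 (LowDim), 249 against 119 (RenBright) and 230.5 against 119.9 (LowBright), and in B 88 against 23.2, 149.5 against 55.0, 223 against 81.8 and 239 against 152. On 6000 simulated cells 93.7% were called, 99.9% of them correctly, and 88.7% of simulated cells with 2 tags were left out. The simulated margins were set near those of A. In B the margins of RenDim, LowDim and LowBright were narrower. The cultures also held a larger share of cells with 2 tags than the simulation, so these rates need not hold for them, least of all for B.

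Counts were summed per hashtag pool, and the 8 sums were the samples of the knockdown analysis. Genes kept by the expression filter of edgeR 4.0.16 were scaled by TMM and tested with its quasi-likelihood F-test in R 4.3.3 (residual df 4), with 1 group per shRNA and initial level and contrasts for shCUX1 against shControl over both levels, within each level, Bright against Dim in shControl, and the interaction. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, at a threshold of 0.05. The same tool gave every adjusted p of a gene. Pools of a replicate share 1 library, and residuals of paired pools correlated between 0.186 and 0.443 over 12178 genes. Pairing therefore held. The planned fit has no block, and a fit with the replicate as a block was an alternative whose values are given where they moved a count more than 1.5 times or changed a call. DESeq2 1.42.0 was run beside edgeR. Lists of genes, 24 of them with 491 genes, were written before the data were examined, as were the comparisons, filters and clustering settings. They were tested by camera of limma 3.58.1 with an inter-gene correlation of 0.01, again with an estimated correlation, and by fry. A list needed at least 5 tested members, and counts are also given with p adjusted over the list alone. Cavin2, Ighm, Lamb4, Ly6g and Trbc2 are absent from the files under those names and were not tested.

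The named genes of tested comparisons were fixed by rule: Cux1, the 10 largest positive and 10 largest negative log2 fold changes among genes past the threshold with a mean of at least 20 UMIs per pool and the same direction in A and B, and from each list with at least 2 such genes the 3 with the smallest p. For unreplicated comparisons the rule took Cux1, the 10 highest and 10 lowest ratios with at least 100 UMIs whose interval excluded 1, and 3 per list farthest from 1; for antibody tags the direction also had to hold in every hashtag pool with at least 100 cells. Predicted, ribosomal, mitochondrial, Xist and Y-linked genes were counted but not named. For antibody tags only the first 5 of 10 at each end are printed, a shortening made after the values were seen.

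LT-HSC and progenitors, cell classes and antibody tertiles were compared as ratios of summed UMIs over total UMIs, with 95% exact conditional binomial intervals for ratios, exact Poisson intervals for rates and Clopper-Pearson intervals for shares. These intervals cover counting error only. A count of 0 is set against a floor of 3 counts, and log2 ratios add 0.5 UMIs. The median ratio of a list was ranked among 10000 random lists drawn from 20 expression bins. Clustering used 2000 variable genes without Cux1 and the fixed-list genes, 30 principal components, 15 neighbours and Leiden at resolution 1 (igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0). A cluster was named when at least 3 markers of 1 of 14 marker lists were up 2-fold or more and seen in 10% of its cells, more than for any other list. A tie went to the list with more markers among the 10 leading genes of the cluster, and no other list was allowed more markers there. A cluster with few UMIs for its library, or led by at least 3 MHC class II genes, also needed 1 of its own markers there. Other clusters were unnamed. Among LT-HSC, 1 megakaryocyte-like and the erythroid-like cluster were named on 3 markers each. Because cells cluster on genes that the knockdown moves, percentages of classes per pool come from a clustering without 3898 called genes. Numbers of cells per pool behind sums over a class come from the main clustering and depend on such genes. The 7 tags were scaled by their sum per cell, and cells were ranked by the share of a tag. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

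The knockdown, the initial level and LT-HSC against progenitors were tested on simulated data with 200 changed genes, of which those with enough counts were compared. The contrasts within Dim or Bright and the interaction were not simulated. For shCUX1 against shControl, 68.7% of genes changed 1.5-fold were recovered, 86.6% of those changed 2-fold and 95.5% of those changed 4-fold, with 14 false calls and 13369 genes tested. For Bright against Dim the values were 49.3%, 76.1% and 93.9%, with 10 false calls and 13377 genes tested. For LT-HSC against progenitors the intervals covered 95.6% of unchanged genes. Replicates A and B differed by more than counting error, with chi-square per degree of freedom of 12.1 (RenDim), 9.47 (LowDim), 14.6 (RenBright) and 12.2 (LowBright).

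Alternatives set beforehand were scaling by total UMIs or by DESeq2, no filter on low counts, at least 2000 UMIs, at most 5% mitochondrial UMIs, doublets kept, HSC-like cells only, a hashtag called when the top tag has at least 5 times the next, Leiden at 0.5 and 1.5, leaving out replicates, and other rankings of the NGFR tag (split at the median, deciles, over the isotype, within strata of depth, within classes). Added after the data were seen were a hashtag rule (background-scaled top tag at least 2 times the next), removal of megakaryocyte-like cells, NGFR without scaling, clustering without called genes, omission of single pools, and additive fits. Cells without a called hashtag were left out of the knockdown analysis, and reads were not available.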

Results

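Cux1 encodes a homeobox transcription factor whose human counterpart lies on chromosome 7q, a region often deleted in myeloid neoplasms. The data came from mouse bone marrow and from 4 gene expression libraries made with the 10x 3' chemistry. In the first experiment, long-term hematopoietic stem cells (LT-HSC) and hematopoietic progenitors of the CUX1 ATPN genotype gave 1 library each, with 7 antibody tags read on the same cells. In the second, LT-HSC were sorted on their initial CUX1 level, an shRNA was induced, and the cells were cultured for 5 days. The hashtag names separate a control shRNA (shControl) from an shRNA against Cux1 (shCUX1), and cells that began Dim (low CUX1) from cells that began Bright (high CUX1). That made 4 pools in each of replicates A and B, or 8 pools. After filtering, the LT-HSC library held 1746 cells with 30954187 UMIs and the progenitor library 9450 cells with 119159469 UMIs. Replicate A held 7118 cells, of which 6212 carried a called hashtag, and replicate B held 7750, of which 6386 did. A pool held between 810 and 2559 cells, and between 11890386 UMIs (shCUX1 Dim, B) and 36975448 UMIs (shControl Dim, B).

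Cux1 mRNA lies on mouse chromosome 5 (GRCm38, 136248135 to 136567490). Replicate A held 39.4 Cux1 UMIs per 1e+06 UMIs (CPM) in shControl Dim, 14.6 in shCUX1 Dim, 33.5 in shControl Bright and 14.7 in shCUX1 Bright. In replicate B the corresponding values were 38.0, 14.5, 32.4 and 13.6. Cux1 fell 2.57-fold in shCUX1 against shControl pools (log2 fold change -1.36, SE 0.058, adjusted p = 2.42e-06, n = 4 pools per shRNA). The loss was of similar size in Dim (log2 -1.44, adjusted p = 7.42e-05) and Bright pools (log2 -1.28, adjusted p = 4.17e-05), and its interaction with the initial level did not pass (log2 0.16, SE 0.11, adjusted p = 0.724). After culture, Cux1 mRNA did not differ detectably between Bright and Dim shControl pools (log2 -0.12, SE 0.076, adjusted p = 0.306), although the cells had been sorted on CUX1 beforehand. All p-values measure only the spread between these pools, and A and B differ in sex by Xist and Y-linked mRNA, so they came from different animals. The labels do not say how many animals each replicate holds, and replicate cannot be separated from sex.

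**Figure D1:**
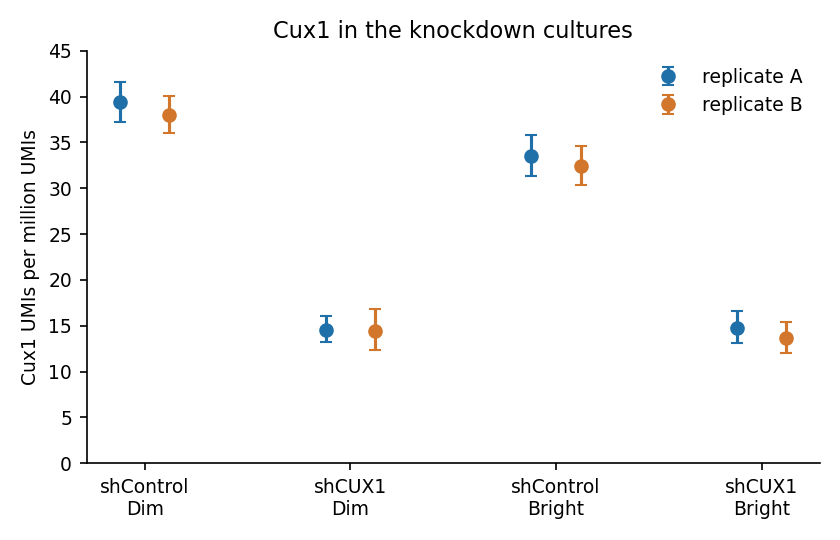
Cux1 CPM (y axis) in the 4 pools of replicates A and B, with 95% Poisson intervals as error bars. The shCUX1 pools lie between 13.6 and 14.7 and the shControl pools between 32.4 and 39.4.

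The first question was which genes change when Cux1 is lowered in cultured LT-HSC. The knockdown pools lost transcripts of the platelet program, the only list that also passed camera with an estimated correlation. Some granulocyte, p53 and glycolysis genes fell, and many G1/S genes rose. Of 13552 genes tested, 2157 passed, 915 up and 1242 down, and 365 of them changed at least 2-fold (122 up, 243 down). With the replicate as a block 3519 passed. For shCUX1 against shControl, scaling by total UMIs gave 1396 up and 966 down, so the balance of up and down rests on the scaling. The genes with the largest gains were Hddc3 (log2 2.73, adjusted p = 8.39e-05), Plcd3 (2.69), Skint3 (2.33), Arhgef25 (2.28), March9 (2.28), Tgfbi (2.27), Gprasp2 (2.19), Tgfbr3 (2.17), Adgrl4 (2.12) and Pdgfd (1.99). Among these, Adgrl4, an adhesion receptor best known from endothelium, rose from 113 to 388 CPM in Dim A and from 44.5 to 276 in Bright A. Tgfbr3, a co-receptor for TGF-beta ligands, rose at an adjusted p of 0.0163. The largest losses were Ccnb1ip1 (log2 -4.78, adjusted p = 6.53e-06), Mcpt8 (-4.09, adjusted p = 1.95e-06), Lrrc32 (-3.48), Gdpd3 (-3.28), Kcnf1 (-3.11), C5ar1 (-3.03), Cd300lb (-2.89), Il1a (-2.83), Ctsg (-2.81) and Il34 (-2.73). Ccnb1ip1 encodes a ubiquitin ligase of meiotic recombination, Mcpt8 a basophil protease and Ctsg a granule protease of neutrophil precursors.

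Within the fixed lists, the megakaryocyte program fell most completely. Of 23 members tested 21 fell and 1 rose, or 22 and 1 adjusted over the list alone (camera adjusted p = 9.83e-61). Treml1, a platelet granule receptor, fell (log2 -1.36, SE 0.048, adjusted p = 9.52e-07), as did Gp5 (-0.93) and Gp9 (-0.85), both subunits of the platelet von Willebrand factor receptor. The riser was Mmrn1 (0.66), named after its value was seen. The list's adjusted p = 0.0237 with an estimated correlation, and 0.0939 when the replicate was also a block. Megakaryocyte-like cells moved with this list: without them 1 of 22 members fell and the median log2 fold change went from -1.03 to -0.15.

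Some myeloid genes fell alongside. In the granulocyte and monocyte program 8 of 19 fell and none rose, or 10 and 1 adjusted over the list alone (camera adjusted p = 1.03e-11, adjusted p = 0.121 with an estimated correlation). Mpo (log2 -1.94, adjusted p = 5.10e-06), Prtn3 (-2.69) and the transcription factor gene Cebpa (-1.55, adjusted p = 0.00123) were among them. Of 11 basophil and mast cell genes, 4 fell and 3 rose, or 5 and 3 adjusted over the list alone (camera adjusted p = 9.52e-04, adjusted p = 0.121 with an estimated correlation), with Cpa3 and Mcpt8 down (-1.36 and -4.09). Without megakaryocyte-like cells 7 granulocyte and monocyte genes of 18 fell, and 2 basophil and mast cell genes fell and 1 rose. Myeloid classes also differed between the shRNAs in Bright pools, with called genes left out of clustering. Monocyte-like cells made up 5.51% of shControl and 0.911% of shCUX1 cells in A. In B no cluster was named monocyte-like, and neutrophil-progenitor-like cells, a name absent from A, made up 14.2% and 20.9%. That name rests on 1 cluster with 3 markers, against 2 for monocyte-like. No cluster of B took it at the lower Leiden resolution. Its leading genes include Ccl3, Ccl4, Ccl5 and Ccl9, as do those of the monocyte-like cluster of A. The names therefore do not match between A and B, and no opposite change of a class can be read from them. In Dim pools the shares of both classes were at most 0.625%. The contrast was not repeated without these classes.

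Part of the p53 targets, glycolytic genes and apoptosis genes also fell. Of 20 p53 targets 13 fell, or 15 adjusted over the list alone (camera adjusted p = 1.03e-11, adjusted p = 0.230 with an estimated correlation), among them the cell-cycle inhibitor gene Cdkn1a (log2 -1.31, adjusted p = 5.43e-04), Ccng1 (-0.68) and Bax (-0.51). Of 20 glycolysis genes 11 fell, or 14 with 1 up adjusted over the list alone (camera adjusted p = 6.98e-06, adjusted p = 0.237 with an estimated correlation), including Egln3 (-0.75), Pgam1 (-0.37) and Aldoa (-0.33). Among 20 apoptosis genes 6 fell and 1 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00181, adjusted p = 0.121 with an estimated correlation), led by Bcl2 (-0.81, adjusted p = 2.98e-05) and Fas (-0.90). Without megakaryocyte-like cells 4 p53 targets, 7 glycolysis genes and 3 apoptosis genes fell.

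Many G1/S genes rose, and a minority of G2/M and HSC identity genes. Of 24 G1/S genes 16 rose and none fell, or 21 adjusted over the list alone (camera adjusted p = 1.19e-09, adjusted p = 0.330 with an estimated correlation), with small changes such as Uhrf1 (log2 0.41), Mcm5 (0.31) and Mcm4 (0.29). For G2/M, 4 of 24 rose, or 7 adjusted over the list alone (camera adjusted p = 9.52e-04, adjusted p = 0.656 with an estimated correlation), including Prc1 (0.41), Ccna2 (0.26) and Birc5 (0.22). In the HSC identity list 8 of 27 rose and 2 fell, also 8 and 2 adjusted over the list alone (camera adjusted p = 0.0116, adjusted p = 0.582 with an estimated correlation). Tcf15 (0.91) and Kit (0.40) rose, whereas Mpl, the thrombopoietin receptor gene, fell (-0.67). Without megakaryocyte-like cells 2 G1/S genes, 1 G2/M gene and 4 HSC identity genes rose. Neither of the latter lists passed fry (adjusted p = 0.130 and 0.149). The other 15 lists did not pass camera: for MHC class II 1 rose and 2 fell of 13, MHC class I 2 and 2 of 15, interferon response 1 and 1 of 22, quiescence 3 and 4 of 20, erythroid 0 and 3 of 16, lymphoid 0 and 3 of 12, PI3K and AKT signalling 1 and 2 of 24, DNA damage repair 4 and 3 of 24, MYC and ribosome biogenesis 3 and 1 of 24, oxidative phosphorylation 0 and 1 of 24, immediate early genes 2 and 2 of 18, NF-kB 1 and 1 of 22, TGF-beta and Notch 0 and 1 of 17, mouse homologs of genes on human chromosome 7 1 and 2 of 15, and the unfolded protein response 0 and 1 of 18. Fry called 11 lists, among them 4 of these 15: oxidative phosphorylation (adjusted p = 0.00396), chromosome 7 homologs (0.0135), erythroid (0.0160) and lymphoid (0.0301), all down. With the replicate as a block, camera also called MYC and ribosome biogenesis (adjusted p = 0.0352) and the unfolded protein response (adjusted p = 0.0193).

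Within the initial levels, 402 genes passed in Dim pools (163 up, 239 down) and 1597 in Bright pools (592 up, 1005 down). With the replicate as a block the counts were 1205 and 2842. Of 23 megakaryocyte genes 9 fell in Dim and 22 in Bright pools, or 18 and 22 adjusted over the list alone. Of 24 G1/S genes 1 rose in Dim and 13 in Bright pools, or 3 and 18 adjusted over the list alone. Such counts do not test a difference between the levels. Camera called 10 of 24 lists in Dim and 11 in Bright pools, of which 0 and 1 passed with an estimated correlation; fry called 9 and 11.

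**Figure D2:**
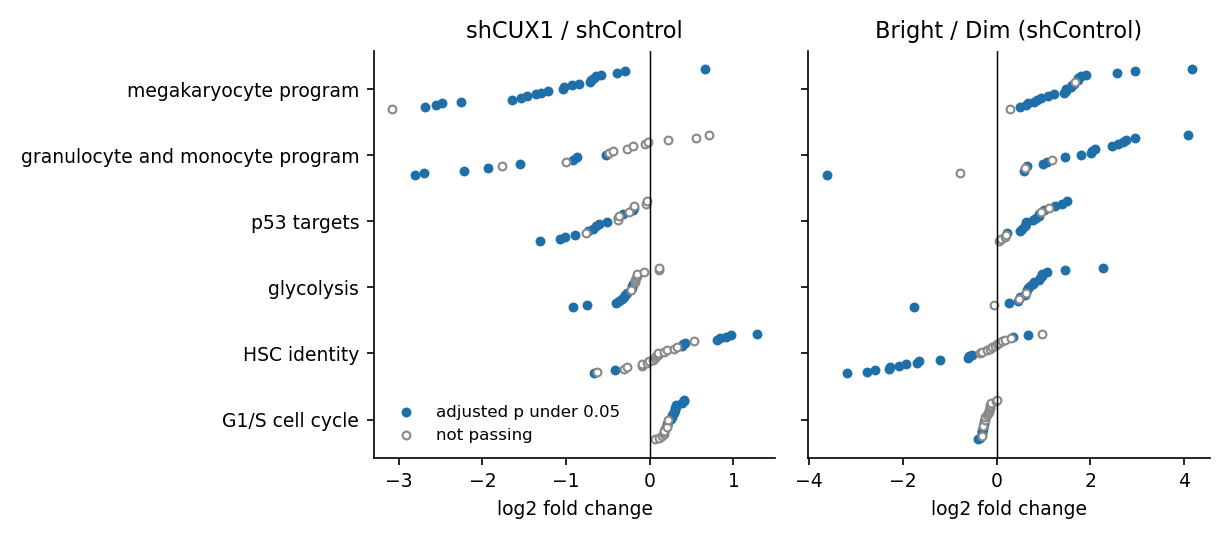
Log2 fold change (x axis) of each tested member of 6 fixed lists (y axis) in shCUX1 against shControl pools (left) and in Bright against Dim shControl pools (right). Filled points passed at an adjusted p under 0.05 and open points did not; 21 of 23 megakaryocyte genes fell on the left and 21 rose on the right.

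Cells that had begun with high CUX1 differed after 5 days from those that had begun with low CUX1, in shControl pools. Bright cultures carried more platelet transcripts, the only list that also passed camera with an estimated correlation. Many granulocyte, glycolysis, inflammatory and MHC class II genes were higher in Bright, and part of the stem-cell genes in Dim cultures. The count was 2788 genes, 1585 higher and 1203 lower in Bright, and 880 changed at least 2-fold (498 higher, 382 lower). With the replicate as a block 4433 passed. Initial CUX1 high against low gave, with scaling by total UMIs, 1154 higher and 2429 lower. The largest gains in Bright were Serpina3i (log2 5.06, adjusted p = 2.07e-04), Serpina3h (4.78), Clec4a1 (4.51, adjusted p = 0.0223, or 0.0502 with the replicate as a block), Saa3 (4.14), F13a1 (4.08), Clec5a (3.98), H2-Eb1 (3.98), Gsta2 (3.96), Gas7 (3.90) and Serpina3b (3.80). The serpin genes encode protease inhibitors, Saa3 is an acute-phase gene and F13a1 a coagulation factor gene of monocytes and platelets. The largest losses were Bcam (-5.05, adjusted p = 0.00517), Wfdc2 (-4.62), Abcg3 (-4.21), Mmp16 (-4.16), Mapk12 (-4.12), Lhcgr (-4.02), Nrk (-3.96), Myof (-3.67), Gfi1 (-3.63) and Tgfbi (-3.46).

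The megakaryocyte program rose in Bright pools for 21 of 23 genes, or 22 adjusted over the list alone (camera adjusted p = 1.75e-46, adjusted p = 0.0223 with an estimated correlation, and 0.0743 with the replicate also as a block). Gp5 (log2 1.60, adjusted p = 4.69e-06), Treml1 (1.59) and Gp9 (1.22) led it. Without megakaryocyte-like cells 1 of 22 rose and the median went from 1.48 to 0.54. In the granulocyte and monocyte program 15 of 19 rose and 1 fell, or 15 and 2 adjusted over the list alone (camera adjusted p = 2.30e-18, adjusted p = 0.0587 with an estimated correlation), with Mpo (2.70, adjusted p = 4.69e-06), Ms4a3 (2.01) and the Fc receptor gene Fcgr3 (1.79). Without megakaryocyte-like cells 13 of 18 rose. Myeloid classes moved with this contrast: with called genes left out of clustering, monocyte-like cells made up 0.0% of Dim and 5.51% of Bright shControl cells in A, and neutrophil-progenitor-like cells 0.625% and 14.2% in B. The latter name rests on 1 cluster with 3 markers, and no cluster of B took it at Leiden resolution 0.5. The contrast was not repeated without these classes. Of 11 basophil and mast cell genes 6 rose and 1 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 5.75e-04, adjusted p = 0.112 with an estimated correlation), with Cpa3 at 1.93. Of 16 erythroid genes 5 rose and 1 fell, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00882, adjusted p = 0.150 with an estimated correlation), with Gata1 at 1.58. Without megakaryocyte-like cells 4 basophil and mast cell genes and 0 erythroid genes rose by edgeR.

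Many metabolic and inflammatory genes were higher in Bright pools. Of 20 glycolysis genes 16 rose and 1 fell (Ldhb, log2 -1.76, named after its value was seen), or 17 and 1 adjusted over the list alone (camera adjusted p = 1.03e-16, adjusted p = 0.0788 with an estimated correlation); Pgam1 (log2 1.08, adjusted p = 5.66e-05), Aldoa (0.96) and Tpi1 (0.90) had the smallest p. In the NF-kB and inflammatory list 11 of 22 rose, or 15 adjusted over the list alone (camera adjusted p = 1.63e-09, adjusted p = 0.175 with an estimated correlation), including Bcl3 (1.89), Il1r1 (1.11) and Birc3 (0.99). MHC class II genes rose for 7 of 13, or 8 adjusted over the list alone (camera adjusted p = 1.48e-05, adjusted p = 0.150 with an estimated correlation), including H2-Ab1 (1.87) and H2-Ob (1.25). In HSC-like cells only, where shControl Bright held 13 cells in A and 31 in B, H2-Ab1 was lower in Bright. Of 20 p53 targets 14 rose, or 17 adjusted over the list alone (camera adjusted p = 1.59e-09, adjusted p = 0.175 with an estimated correlation), including Btg2 (1.24, adjusted p = 1.90e-04) and Bbc3 (0.91). Immediate early genes (8 of 18 with camera adjusted p = 4.22e-04, adjusted p = 0.404 with an estimated correlation), the unfolded protein response (8 of 18, or 12 adjusted over the list alone with camera adjusted p = 0.00128, adjusted p = 0.306 with an estimated correlation) and apoptosis (9 of 20 with camera adjusted p = 0.00222, adjusted p = 0.116 with an estimated correlation) also rose. Without megakaryocyte-like cells 15 glycolysis, 9 NF-kB, 6 MHC class II, 2 p53, 1 immediate early, 2 unfolded protein response and 4 apoptosis genes rose.

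Part of the stem-cell and cell-cycle genes were higher in Dim pools. The HSC identity list fell in Bright for 13 of 27 genes and rose for 2, or 14 and 3 adjusted over the list alone (camera adjusted p = 2.76e-10, adjusted p = 0.173 with an estimated correlation). Tcf15 (log2 -2.09, adjusted p = 1.19e-04), Mecom (-1.93) and Hoxa9 (-1.22), all transcription factors of stem cells, fell. HSC-like cells moved with this list. With called genes left out of clustering, they made up 19.8% of Dim and 7.02% of Bright shControl cells in A, and 20.4% and 10.7% in B. Of 24 genes each, 12 G2/M genes fell, or 17 adjusted over the list alone (camera adjusted p = 1.59e-05, adjusted p = 0.404 with an estimated correlation), 10 G1/S genes fell, or 13 (camera adjusted p = 1.54e-04, adjusted p = 0.404 with an estimated correlation), and 5 DNA damage repair genes fell, or 7 (camera adjusted p = 0.00882, adjusted p = 0.306 with an estimated correlation). Cdc20 (-0.36), Dhfr (-0.31) and Mcm4 (-0.30) were among them. Without megakaryocyte-like cells 11 HSC identity genes fell and none of the G1/S, G2/M or DNA damage repair genes passed in edgeR. Camera called 15 of 24 lists, 1 with an estimated correlation and 16 with the replicate as a block, which added MYC and ribosome biogenesis (adjusted p = 0.0106); fry called 18. The 9 lists that camera did not call were MHC class I (4 rose and 2 fell of 15), interferon response (2 and 3 of 22), quiescence (3 and 3 of 20), lymphoid (4 and 1 of 12), PI3K and AKT signalling (1 and 1 of 24), MYC and ribosome biogenesis (0 and 3 of 24), oxidative phosphorylation (1 and 0 of 24), TGF-beta and Notch (5 and 1 of 17) and chromosome 7 homologs (3 and 1 of 15). Fry called lymphoid (adjusted p = 0.0467), TGF-beta and Notch (0.0267) and chromosome 7 homologs (0.0467) among them.

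The same contrast in shCUX1 pools was outside the plan and was run only with and without the replicate as a block. It called 1589 genes (856 higher and 733 lower in Bright, and 2697 with the block), and 15 lists by camera, of which 0 passed with an estimated correlation. There 9 of 23 megakaryocyte genes and 7 of 12 lymphoid genes rose, and 14 of 27 HSC identity genes and 0 of 24 G1/S genes fell. Such counts do not test a difference between the shRNAs.

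The contrast between shRNAs and the contrast between levels share the shControl pools. They opposed each other across 12184 genes (covariance -0.124, against 0.00596 from simulated unchanged genes; Pearson r = -0.595, where genes are not independent replicates). Genes up with shCUX1 and lower in Bright numbered 381 (81.2 if independent), and genes down with shCUX1 and higher in Bright 727 (145 if independent). In the same direction, 24 genes were up in both (107 if independent) and 25 down in both (110 if independent).

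Whether the knockdown acts differently by initial level was tested by the interaction. Some platelet genes lost more in Bright than in Dim pools over all cells, whereas the fall of Flt3 passed in Dim pools only. The interaction passed for 37 genes (10 up, 27 down), and 304 with the replicate as a block. Gp9 was lowered in Bright pools (log2 -1.44) and did not pass in Dim (-0.26, adjusted p = 0.0871, or 0.0270 with the replicate as a block), with an interaction of -1.18 (adjusted p = 0.00429). Lmna, a nuclear lamina gene, fell in Bright (-1.23) and did not pass in Dim (0.47, adjusted p = 0.0582, or 0.0198 with the replicate as a block, interaction -1.70, adjusted p = 0.00478). Flt3, a receptor of lymphoid-primed progenitors, fell in Dim (-1.19, adjusted p = 0.00761) and did not pass in Bright (0.32, adjusted p = 0.209, interaction 1.51, adjusted p = 0.0335). Gpr183, a chemotactic receptor gene, rose in Bright (2.66, adjusted p = 1.35e-04) and did not pass in Dim (0.66, interaction 2.01). Of 23 megakaryocyte genes 4 had a negative interaction, or 15 adjusted over the list alone (camera adjusted p = 1.28e-31, adjusted p = 0.0395 with an estimated correlation, and 0.0933 with the replicate also as a block). Inside megakaryocyte-like cells the median log2 ratios of the list were -0.96 and -0.96 in Dim and -1.18 and -1.14 in Bright (A and B). The Dim medians rest on few shCUX1 cells, as 1744 of 1752 in A and 783 of 810 in B lay outside the class. These medians do not test the interaction inside the class. In the lymphoid list Flt3 and Ikzf1 had a positive one, or 3 of 12 adjusted over the list alone (camera adjusted p = 1.55e-05, adjusted p = 0.173 with an estimated correlation). Without megakaryocyte-like cells edgeR called no interaction gene.

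LT-HSC and progenitors, the first experiment's populations, were compared without replicates, so their values are descriptive. LT-HSC carried stem-cell, platelet and interferon transcripts, and progenitors carried myeloid, lymphoid, erythroid and cell-cycle transcripts. Cux1 mRNA made up 42.3 CPM in LT-HSC and 37.9 in progenitors (1308 and 4511 UMIs, ratio 1.12, 95% interval 1.05 to 1.19), but this ratio was of the same order as the gap between scalings, and the direction reversed with cells thinned to 5000 UMIs (log2 -0.038) and as the mean of per-cell shares (-0.11). By hashtag Cux1 was 36.1, 52.2, 50.7 and 34.2 in LT-HSC and 34.2, 45.1, 39.1 and 33.0 in progenitors, so LT-HSC were higher in 4 of 4 and the same hashtags were high in both. Only for the third hashtag did the 95% intervals stay apart (45.3 to 56.5 against 37.0 to 41.3). The labels do not say whether a hashtag marks the same animals in both libraries. The highest ratios belonged to Gkn3 (199 against 2 UMIs, ratio 383, interval 105 to 3185), Cyp26b1 (142 against 2, ratio 273, interval 74.3 to 2279), Slc17a8 (137), Tm4sf1 (99 against 3, ratio 127, interval 42.2 to 627), Hoxb8 (119), Glipr1l1 (92.9), Evc2 (86.3), Smtnl1 (85.2), Ncam2 (68.5) and Inhba (54.4). Cyp26b1 encodes an enzyme that degrades retinoic acid. Vpreb3, a pre-B cell gene, had 0 UMIs in LT-HSC and 1144 in progenitors, and Cd300lb had 0 and 998; Rab7b, Col19a1, Acsl6, Ifi205, Abca9, Cd300c, Pdcd1 and Slamf6 likewise had 0 in LT-HSC. A count of 0 there allows up to 0.0969 CPM.

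By list, HSC identity genes were higher in LT-HSC for 26 of 28 (median log2 ratio 1.59), led by Sox18 (36.4-fold), Tcf15 (18.9-fold) and Slamf1 (15.1-fold). Megakaryocyte genes were higher for 19 of 20 (median 2.17; Mmrn1 16.3-fold, Vwf 8.42-fold). Interferon response genes were higher for 21 of 23 (median 0.74; Iigp1 4.48-fold, Gbp2 3.00-fold), and quiescence genes for 13 of 20 (median 0.47; Ndn 14.1-fold and Cdkn1c 13.8-fold, whereas Gfi1 was 5.86-fold higher in progenitors). These medians lay at percentiles 100.0, 100.0, 100.0 and 99.98 of random lists matched on expression. Immediate early genes lay at percentile 99.95 (14 of 19 higher, with Egr1 3.97-fold, whereas Hspa1a and Btg2 were lower, at ratios of 0.278 and 0.312). Progenitors had more of 23 of 24 G1/S genes (median -0.72; Ccne1 4.29-fold) and of all 24 G2/M genes (median -0.68; Birc5 2.40-fold). Granulocyte and monocyte genes were higher in progenitors for 23 of 24 (median -5.63; Mpo 247-fold), lymphoid genes for 16 of 17 (median -3.30; Dntt 1730-fold, 6 against 39909 UMIs), erythroid genes for 15 of 19 (median -1.62; Gypa 28.8-fold) and basophil and mast cell genes for 7 of 10 (median -3.68; Hdc 46.0-fold); these 6 medians lay at percentile 0.0. MYC and ribosome biogenesis, DNA damage repair, the unfolded protein response and apoptosis leaned to progenitors (percentiles 0.370, 1.41, 3.11 and 1.61), TGF-beta and Notch to LT-HSC (97.4), and MHC class I and II, PI3K and AKT, p53, oxidative phosphorylation, glycolysis, NF-kB and chromosome 7 homologs lay between percentiles 8.88 and 88.4. Scaling by TMM lowers every log2 ratio by 0.124, and median-ratio scaling by 0.137.

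Cux1 mRNA differed across cell classes. Among classes of the progenitor library, with unnamed clusters pooled, it was highest in HSC-like cells, at 76.1 CPM (interval 71.2 to 81.2; 1792 cells), followed by lymphoid-primed-like cells (58.4), megakaryocyte-like cells (47.9), unnamed cells (45.3), basophil/mast-like cells (40.4) and B-lymphoid-like cells (24.6). It was lowest in neutrophil-progenitor-like (13.7), monocyte-like (13.3) and erythroid-like cells (12.7). The latter pools 3 clusters of 14.2, 7.09 and 34.4 CPM, the last of 237 cells. Lymphoid-primed-like cells likewise pool clusters of 67.6, 54.4 and 33.6 CPM, the last of 234 cells. Of the single unnamed clusters, 1 of 41 cells had 128 CPM, 1 of 357 cells 6.50 and 1 of 67 cells 12.2 (7 UMIs), outside the range of the classes. A T/NK-like class of 20 cells held 1 Cux1 UMI. Among pooled classes of the LT-HSC library the HSC-like class had the lowest value, 26.4 (interval 19.6 to 34.8, 161 cells). Erythroid-like cells had 34.7, megakaryocyte-like cells 38.3 and unnamed cells 46.0. The megakaryocyte-like class pools clusters of 25.4 (115 cells) and 47.9 CPM (112 cells), and 1 unnamed cluster of 102 cells had 24.7. At Leiden resolution 1.5 the HSC-like class had the highest value, 45.7, against 34.5, 39.4 and 43.2, so its rank rests on the clustering. Summed over both shRNAs, HSC-like cells of the knockdown cultures had 21.9 in replicate A and 40.9 in B, where unnamed cells had 30.1 and 28.5; megakaryocyte-like cells had 19.3 and 20.5, and neutrophil-progenitor-like cells 21.6 and 23.3. Monocyte-like cells of A had 18.9 and erythroid-like cells of B 31.5. Cux1 did not differ between HSC-like and other cells of the cultures (log2 0.032, SE 0.27, not passing), with opposite signs in A (-0.45) and B (0.43). The class sums over both shRNAs, in a mix that differs between A and B. In the main clustering HSC-like cells of A were 619 shControl Dim (38.0 Cux1 CPM), 983 shCUX1 Dim (13.5), 13 shControl Bright and 55 shCUX1 Bright. Those of B were 567 (49.2), 231 (18.0), 31 and 54. In Dim A both values lie near those of all cells of the same pools (39.4 and 14.6) and in Dim B above them (38.0 and 14.5). As HSC-like cells came mostly from Dim pools, the class contrast is also confounded with the initial level. HSC identity genes name this class, so their rise in it is given by the naming and is left out, and megakaryocyte genes name some of the other cells. Over that class contrast, 13 of 22 interferon genes were higher (camera adjusted p = 1.08e-05, adjusted p = 0.561 with an estimated correlation), 20 of 23 megakaryocyte genes lower (2.77e-45 and 0.312), 17 of 20 p53 targets lower (7.31e-14 and 0.312) and 15 of 20 glycolysis genes lower (4.78e-07 and 0.312). Adjusted over the list alone these counts were 14, 22, 17 and 15.

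**Figure D3:**
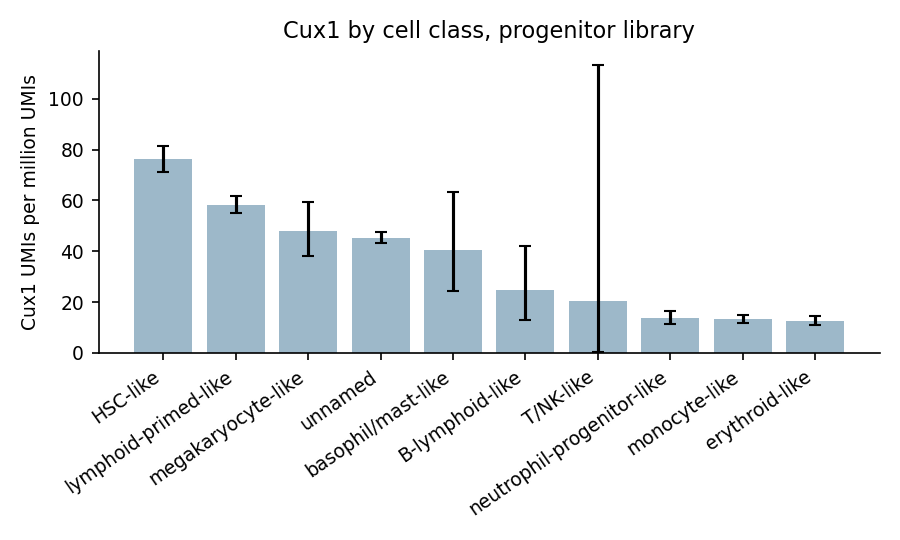
Cux1 CPM (y axis) per cell class of the progenitor library, with 95% Poisson intervals as error bars. HSC-like cells are highest at 76.1 and erythroid-like cells lowest at 12.7; the interval of the T/NK-like class is wide because it rests on 1 UMI.

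Most LT-HSC clusters had too few markers to name: 72.2% of cells were unnamed, 227 cells were megakaryocyte-like, 9.22% HSC-like and 5.56% erythroid-like, and of these a megakaryocyte-like and the erythroid-like cluster were led by mitotic and histone genes. Progenitors were 21.8% lymphoid-primed-like, 19.0% HSC-like, 11.0% monocyte-like, 9.68% erythroid-like, 4.56% neutrophil-progenitor-like, 1.44% megakaryocyte-like and 31.3% unnamed. The cultures held 24.3% HSC-like and 3.93% megakaryocyte-like cells in A, and 12.7% and 5.79% in B. With the genes called in any comparison left out of clustering, HSC-like cells made up 19.8% of shControl Dim, 26.7% of shCUX1 Dim, 7.02% of shControl Bright and 6.92% of shCUX1 Bright in A, and 20.4%, 19.3%, 10.7% and 11.4% in B. Megakaryocyte-like cells in the same order made up 1.03%, 0.400%, 8.30% and 1.55% in A, and 10.2%, 12.8%, 14.8% and 8.44% in B, where the name rests on other clusters than in A. At Leiden resolution 0.5 the class held 254 of 2037, 210 of 1752, 397 of 1325 and 251 of 1098 cells in A, and 10.4%, 12.7%, 14.7% and 8.30% in B, so the size of the class in A, and of its drop in Bright pools, rests on the resolution.

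The antibody against NGFR, which the feature table calls sCux1, was read on cells of the first experiment. Its share of all antibody UMIs had opposite relations to Cux1 mRNA in the populations, and in progenitors the direction reversed with the scaling. In LT-HSC, cells in the upper tertile by NGFR share had 43.7 Cux1 CPM and those in the lower tertile 35.3 (ratio 1.24, interval 1.07 to 1.44, 582 cells each). By hashtag pool the LT-HSC ratios were 1.36 (1.03 to 1.81), 1.16 (0.868 to 1.56), 1.27 (0.935 to 1.73) and 1.02 (0.738 to 1.43). They lay above 1 in 4 of 4 pools, but only the first interval excluded 1. In progenitors the upper and lower tertiles had 22.5 and 55.0 CPM (ratio 0.410, interval 0.380 to 0.442, 3150 cells each, below 1 in 4 of 4 pools). Ranked by NGFR over the isotype control the ratios were 1.35 and 1.93, and by NGFR UMIs without scaling 1.74 and 3.07. Drawn within each class they were 1.22 and 0.923. Upper-tertile cells were deeper, with a median of 18487.5 against 13131.5 UMIs in LT-HSC and 16472 against 7954.5 in progenitors.

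**Figure D4:**
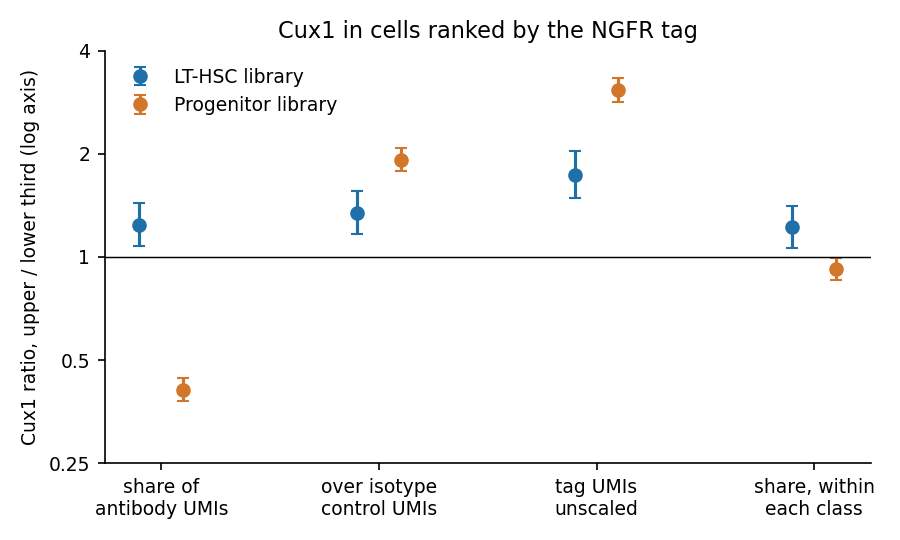
Ratio of Cux1 CPM in the upper over the lower tertile of cells by NGFR (log axis) under 4 rankings, in LT-HSC and progenitors, with 95% intervals. In progenitors the ratio is 0.410 by share of antibody UMIs and 3.07 by NGFR UMIs without scaling.

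LT-HSC with a high NGFR share carried proliferation and erythroid transcripts over all cells. Cell classes moved with this ranking: HSC-like cells made up 0.344% of the upper and 26.5% of the lower tertile, and megakaryocyte-like cells 22.3% and 3.61%. All 24 G1/S genes (median log2 ratio 1.05; Uhrf1 2.76-fold) and all 24 G2/M genes (median 1.37; Ube2c 3.29-fold, Plk1 3.20-fold) were higher, as were 13 of 13 erythroid genes (median 0.94). The G2/M direction turned inside the megakaryocyte-like class, the largest named one, where 0 of 24 were higher and 24 lower (median -0.52). The erythroid direction depended on the scaling, with 7 of 13 higher by NGFR UMIs without scaling (median 0.057). The highest ratios were Car1 (1438 against 2 UMIs, ratio 495, interval 137 to 4090, reversed without scaling), Ms4a3 (8.12), Emilin2 (6.71), Gata1 (6.19) and Fgf3 (6.01). Lower were 24 of 28 HSC identity genes (median -0.53; Procr ratio 0.167, Fgd5 0.219), 22 of 23 interferon genes (median -0.86; Ifit3 0.255), 9 of 11 MHC class II genes (median -0.64; Cd74 0.0625) and 15 of 19 quiescence genes (median -0.76). Quiescence turned inside the megakaryocyte-like class, with 6 of 10 higher (median 0.18), and over the isotype 7 of 11 MHC class II genes were lower (median -0.077). The antibody sum behind the share includes the CD201 and class II tags, whose upper tertiles carried more Procr and H2-Ab1 mRNA (7.75 and 2.02 times). Low Procr and MHC class II mRNA can thus follow in part from the ranking itself. Over the isotype 24 of 28 HSC identity genes (median -0.29) and 19 of 22 interferon genes (median -0.41) stayed lower. The lowest ratios were Inhba (1 against 104 UMIs, ratio 0.00662, interval 1.66e-04 to 0.0377), Cyp26b1 (2 against 128, ratio 0.0108, interval 0.00129 to 0.0397), Ramp2 (0.0256), Pdgfc (0.0330) and Igf1 (0.0362).

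In progenitors a high NGFR share went with myeloid and erythroid transcripts. Of 24 granulocyte and monocyte genes 21 were higher (median log2 ratio 2.15; Fcnb 36.0-fold, S100a8 33.6-fold), as were 17 of 17 erythroid genes (median 2.65; Car1 13.1-fold, Ermap 11.0-fold, Aqp1 9.28-fold). Gml2 (125 against 1 UMIs, ratio 69.3, interval 12.2 to 2758), Camp (67.6), S100a9 (60.0), Ngp (44.1) and Chil3 (42.5) had the highest ratios. Lower were 23 of 26 HSC identity genes (median -1.41; Fgd5 ratio 0.0577, Procr 0.0825, Ly6a 0.0921), 23 of 23 interferon genes (median -1.71; Ifit3 0.0604, Iigp1 0.0833) and 12 of 12 MHC class II genes (median -2.13). Gria2 (0 against 132 UMIs), Prss34 (0.00524), Cd74 (0.00946), H2-Eb1 (0.0131) and Ntng1 (3 against 97 UMIs, ratio 0.0171, interval 0.00348 to 0.0516) had the lowest. The antibody sum again includes the CD201 and class II tags, so low Procr and MHC class II mRNA can follow in part from the ranking itself. Cell classes moved with this ranking: monocyte-like cells made up 24.1% of the upper and 1.81% of the lower tertile, HSC-like cells 4.98% and 31.8%, and lymphoid-primed-like cells 10.1% and 29.0%. Most of the progenitor genes named here reversed when cells were ranked over the isotype or without scaling, and so did most lists. Over the isotype and without scaling, 0 and 0 of 17 erythroid genes were higher (medians -1.50 and -2.23), 3 and 2 of 24 granulocyte and monocyte genes (-0.71 and -2.39), 25 and 25 of 26 HSC identity genes (0.69 and 1.34) and 20 and 22 of 23 interferon genes (0.10 and 0.55). MHC class II genes stayed lower for 7 of 12 in both (-0.43 and -0.19). Inside the lymphoid-primed-like class, the largest named one, the myeloid and erythroid directions also turned, with 5 of 15 granulocyte and monocyte genes (median -0.10) and 3 of 8 erythroid genes (median -0.34) higher.

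Other tags were compared with their own mRNA in the same way. In LT-HSC, cells in the upper tertile by CD201 share had 7.75 times the Procr mRNA of the lower tertile (interval 6.66 to 9.05), CD86 3.02 times the Cd86 mRNA (2.03 to 4.58) and the class II antibody 2.02 times the H2-Ab1 mRNA (1.76 to 2.32), against 1.04, 0.981 and 0.888 when ranked by the isotype control. CD274 gave 1.03 for Cd274 (0.880 to 1.22, isotype 0.885). CD74 gave 0.467 for Cd74 (isotype 0.768). In progenitors the ratios were 8.36 for Cd86 (isotype 0.454), 4.16 for H2-Ab1 (isotype 0.428), 1.55 for Procr (isotype 0.316), 0.672 for Cd274 (isotype 0.419) and 0.140 for Cd74 (isotype 0.222), and the last of these also reversed without scaling, as did Cd274.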

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

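All tests weighed here were written after related values had been seen, except that of the shared shControl pools, which was written beforehand.

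The knockdown differed by initial CUX1 level for 37 genes by the interaction test. Of genes with a more positive effect in Bright pools, Gpr183 (log2 2.01), Flt3 (1.51), Plac8 (1.10), Hvcn1 (1.07), Tespa1 (0.99), Bex6 (0.95), Adgrg3 (0.66), Ikzf1 (0.61) and Ivns1abp (0.53) were named. With a more negative effect were Mt2 (-3.12), Cdkn2a (-2.58), Lyz1 (-2.46), Lmna (-1.70), Exoc3l4 (-1.52), Rhoj (-1.23), Gadd45g (-1.20), Gp9 (-1.18), Elovl7 (-1.08), Rbpms2 (-1.07), Alox5ap (-0.87) and Gp5 (-0.84). Plac8 and Cdkn2a no longer passed with the replicate as a block (adjusted p = 0.0570 and 0.0835). Camera called the interaction for the megakaryocyte program (adjusted p = 1.28e-31), the lymphoid program (1.55e-05), DNA damage repair (0.00560), the unfolded protein response (0.00560), G1/S (0.0165) and the basophil and mast cell program (0.0479, or 0.0852 with the replicate as a block), of which only the megakaryocyte program passed with an estimated correlation (0.0395; the others 0.173, 0.520, 0.624, 0.966 and 0.463).

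UMIs of mCherry appeared in the shControl pools, outside the main measurement. Replicate A held 19 in Dim and 9 in Bright, and replicate B 19 in Dim and 7 in Bright, against 2 and 1 in the shCUX1 pools of A and 0 in those of B. The cultured cells are labelled as carrying an mCherry allele of CUX1. Over the pools mCherry was lower with shCUX1 (log2 -3.36, SE 0.64, adjusted p = 0.00673 by edgeR), and the first experiment held 0.

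Megakaryocyte genes were lower in shCUX1 pools, as were their UMIs over all cells: in Dim 2912 against 5455 CPM in A and 3737 against 5895 in B, in Bright 5182 against 14577.5 and 6179 against 14591.5. Scaling by TMM is excluded as the source, since 21 members still fell with scaling by total UMIs. Fewer megakaryocyte-like cells remain open, since 1 member fell without those cells, which are themselves named on such genes. In the main clustering these cells held a larger part of the UMIs than of the cells. Without them shControl Bright kept 1177 of 1325 cells but 17836138 of 26429436 UMIs in A. In B it kept 1457 of 1631 cells but 16672964 of 27177178 UMIs. The shCUX1 Bright pools kept 17426271 of 19202888 UMIs in A and 14599387 of 19280783 in B. With called genes left out of clustering the class was not smaller in Dim B (10.2% of shControl and 12.8% of shCUX1 cells), where other clusters carry the name than in A. It was smaller with shCUX1 in the other pairings. The values argue against a lower number with unchanged levels over the class as a whole. Inside megakaryocyte-like cells the median log2 ratio was below 0 in every pairing, and the highest of the 4 values was -0.961. That value, of Dim A, rests on few cells, as 1744 of the 1752 shCUX1 cells lay outside the class. The class pools clusters of 225 and 55 cells in A and of 381 and 68 cells in B. A shift between these clusters was not tested. It could lower the medians with unchanged levels inside each cluster, so it remains open.

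Grouping of the pools by chance was tested by other splits. With the initial level as a term, the real split called 1798 genes and the highest of the others, which separates the replicates, 85. Of 34 splits 1 reached the real count, the real one. The replicates pair the pools, and the 8 splits that part the shRNAs of every level and replicate, where the highest other called 0 genes, are too few for a share under 0.05. Plain splits of the 8 pools had been seen first: the shRNA split called 38 genes, the replicate split 55 and the level split 1892.

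Cux1 mRNA was lower in progenitors with a high NGFR share (ratio 0.410). The other tags in the denominator remain open as a source, since ranking by NGFR UMIs without scaling gave 3.07. Cell classes also remain open, since tertiles drawn within each class gave 0.923. HSC-like cells had a median of 140 NGFR UMIs but a share of 38.4%, and monocyte-like cells 67 and 64.0%. The tables therefore give no direction for NGFR against Cux1 mRNA in progenitors that holds across rankings.

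The knockdown and initial-level contrasts opposed each other across genes (covariance -0.124). Shared shControl pools are excluded as the only source: with the knockdown contrast of 1 replicate set against the level contrast of the other, the correlations were -0.470 and -0.618. Simulated unchanged genes, with the same pools shared, had a covariance of 0.00596, so sharing was an unlikely source from the outset. Both contrasts may reflect a common axis from stem-cell to platelet and myeloid mRNA, or an effect of Cux1 itself. Against a direct effect of remaining Cux1 mRNA stands the level contrast, where Cux1 did not pass (log2 -0.12). Which of these holds stays open.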

How the results depend on the processing

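Of 3820 alternative values for 351 results under 39 settings, 2945 kept their direction and side of the threshold or stayed within the interval, 430 were weaker, 6 stronger, 372 moved and 67 reversed. The cause was not tested unless stated. Scaling by total UMIs or DESeq2, at least 2000 UMIs, at most 5% mitochondrial UMIs and doublets kept left the knockdown genes named in the text as they were. Under total UMIs the median log2 fold change of all genes for Bright against Dim shifted by -0.111, to -0.11.

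With the replicate as a block, which removes a source of spread, the counts rose to 3519 (knockdown), 1205 (Dim), 2842 (Bright), 4433 (initial level) and 304 (interaction). Apart from the calls given beside their genes and lists, the block changed no call named in the text. With no filter on low counts the interaction count was 110, and DESeq2 gave 174. In HSC-like cells only, which are fewer, the counts were 7, 21, 0, 0 and 0 in that order. Without megakaryocyte-like cells they were 859, 161, 154, 1021 and 0. With a hashtag called only when the top tag had at least 5 times the next they were 422, 31, 508, 245 and 0. That rule left few cells, 11, 49, 238 and 175 in A and 47, 45, 168 and 276 in B (RenDim, LowDim, RenBright and LowBright). With a background-scaled top tag Dim gave 225 and the interaction 10. Camera with an estimated correlation called 1 list for the knockdown, 0 in Dim, 1 in Bright, 1 for the level and 1 for the interaction, and fry 1 for the interaction.

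Leaving out single pools, where a lone pool is assumed to vary like the other groups, gave 76 to 531 genes in Dim, 544 to 1677 in Bright, 1179 to 3064 for the level and 10 to 53 for the interaction. Over all omissions the knockdown ranged from 367 to 2015, the lowest values coming from additive fits without replicate A (367) or B (420). The knockdown count was 1252 without RenDim A, 1288 without RenBright A and 1176 without RenDim B. In Dim it was 94 without RenDim A, 84 without LowDim A and 76 without RenDim B, and in Bright 544 without RenBright A, 815 without LowBright A and 950 without RenBright B. The level count was 1179 without RenDim A, 1262 without RenBright A and 1405 without RenDim B. The interaction count was 12 without RenDim A, 10 without RenBright A, 24 without LowBright A, 12 without RenDim B, 16 without LowDim B and 20 without RenBright B. The level and interaction without a whole replicate, planned beforehand, were not run, as each group would keep 1 pool. In HSC-like against other cells Cux1 was -0.45 without B and 0.43 without A, where the mix of shRNAs in the class differs.

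In HSC-like cells only, Pgam1 reversed for shCUX1 against shControl (0.16), Lmna in Bright (1.10), and for initial CUX1 high against low H2-Ab1 (-0.81), H2-DMb1 (-0.24), Dhfr (0.23), Mcm6 (0.18) and Treml1 (-0.11). The Knockdown by initial CUX1 level interaction reversed for Plac8 (-1.83), Hvcn1 (-0.55), Lyz1 (0.12), Lmna (0.57), Rhoj (0.065), Rbpms2 (0.11) and Alox5ap (0.099), and with the top tag at 5 times the next for Plac8 (-0.55). Without megakaryocyte-like cells Gp5 was 0.058 for shCUX1 against shControl and Lmna 0.34 in Bright.

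Cux1 per pool moved with the top tag at 5 times the next to 51.0 (RenDim A), 28.9 (RenBright A), 17.3 (LowBright A), 17.6 (LowDim B) and 29.0 (RenBright B) CPM, and with the background-scaled tag to 28.4 (RenBright A). The former rule left between 11 (RenDim A) and 276 cells (LowBright B) per pool. For the LT-HSC library against progenitor library, the log2 ratio of Cux1 was 0.035 under TMM and 0.022 under median-ratio scaling, and it reversed with cells thinned to 5000 UMIs (-0.038) and as the mean of per-cell shares (-0.11). Cux1 in HSC-like cells was 45.7 in LT-HSC, the highest instead of the lowest class there, and 69.5 in progenitors at Leiden resolution 1.5, and 28.9 in Knockdown B at 0.5. At 0.5 the HSC-like share was 15.9% in LT-HSC, 26.3% in progenitors and 6.99% in Knockdown B.

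In LT-HSC ranked by NGFR, Cux1 had a log2 ratio of 0.74 by deciles and 0.80 without scaling. Hmmr reversed within strata of depth (-0.048) and, within classes, Ube2c (-0.41), Plk1 (-0.40) and Hmmr (-0.61) did. Without scaling Car1 (-1.74) and Klf1 (-0.32) reversed.

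In progenitors ranked by NGFR, Cux1 was -0.90 split at the median, -1.82 by deciles, -0.63 within strata and -0.12 within classes. It reversed over the isotype (0.94) and without scaling (1.62). Reversed over the isotype and without scaling were Gml2 (-0.66 and -2.57), Camp (-0.31 and -4.01), S100a9 (-0.73 and -3.46), Chil3 (-0.27 and -5.36), Gria2 (0.85 and 0.22), Ntng1 (1.28 and 0.92), Ifit3 (0.060 and 0.0070), Iigp1 (0.63 and 1.33), Ifi44 (0.52 and 1.21), Fgd5 (0.67 and 2.13), Procr (0.83 and 1.88), Ly6a (0.71 and 1.45), Car1 (-1.46 and -1.86), Ermap (-1.59 and -2.37), Aqp1 (-1.50 and -2.26), Fcnb (-0.91 and -3.45) and S100a8 (-0.53 and -3.17). Ngp reversed without scaling (-3.44) and split at the median (-0.25), and within classes Ermap (-0.11) and Aqp1 (-0.091) did.

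For antibody tags against their own mRNA without scaling, the log2 ratios in LT-HSC were -0.40 (CD74) and 0.31 (CD274). In progenitors they were 2.75 (CD201) and 2.33 (ClassII), and reversed for CD74 (1.33) and CD274 (1.68). Split at the median they were -0.87 (CD74), 2.16 (CD201) and 0.67 (ClassII) in LT-HSC, and -1.86 (CD74), 2.15 (CD86), 0.36 (CD201), -0.37 (CD274) and 1.62 (ClassII) in progenitors. In simulations 49.3% of 1.5-fold changes were recovered for the level; depth itself was not varied.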

Other observations

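Sex-linked mRNA separated the replicates of the cultures, so the replicates differ in sex as well as in library. Replicate A held between 0.0 and 0.0521 CPM of Xist and between 181 and 192 CPM of Y-linked genes. Replicate B held between 586 and 671 CPM of Xist and between 0.311 and 0.595 CPM of Y-linked genes. In the first experiment Xist lay between 622 and 886 CPM.

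Genes called at least 2-fold with shCUX1 were placed on the genome in windows of 10 Mb. Of 12998 tested genes with a position, 355 were such genes. The window with most of them lay on chromosome 14 from 50 to 60 Mb, with 8 of 105 tested genes, among them Mcpt8, Ccnb1ip1 and Ctsg. As many or more fell in 1 window in 55.99% of 10000 shuffles.

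In the first experiment the NGFR tag had a median of 125.5 UMIs per cell in LT-HSC and 118 in progenitors, and the isotype control 1 and 2. Within the megakaryocyte-like class of the LT-HSC library the NGFR tertiles had a Cux1 ratio of 0.909 (0.651 to 1.27), and within lymphoid-primed-like progenitors 1.10 (0.957 to 1.26). Both intervals include 1.

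With called genes left out of clustering, monocyte-like cells made up 5.51% of shControl Bright and 0.911% of shCUX1 Bright cells in A, and neutrophil-progenitor-like cells 14.2% and 20.9% of the same pools in B. In the Dim pools these shares were 0.0% and 0.0571% in A, and 0.625% and 0.617% in B. At Leiden resolution 0.5, the only other one run for this clustering, no cluster of B took the latter name. In the main clustering, Knockdown A held a megakaryocyte-like cluster of 55 cells with a median of 1754 UMIs, and Knockdown B a cluster of 68 cells with a median of 113326.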
